A study of Homo sapiens with 18 samples.

How the data were processed

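RNA-seq was deposited for 18 samples of the MDS-L line as count tables, with 12 libraries in the inhibitor table and 6 in the knockout table. Per the labels' protocols, cells were grown with IL-3 at 10 ng/mL and the inhibitor was given at 3 µM for 8 h or 20 h. PU.1 was edited with Cas9 and synthetic guide RNAs, and neither the guides each sample carried nor the editing efficiency is given in the sources used here. Per the labels, MDS-L libraries were made with a stranded mRNA kit and sequenced as 50-bp read pairs on an Illumina NovaSeq. The RNA of all samples was labelled as poly(A) RNA. Transcripts without a poly(A) tail were abundant in the knockout table and scarce in the inhibitor table, so a single library method for both could not be assumed. Per the submitters' processing notes, bcl2fastq 2.20, FastQC 0.11.8, Trimmomatic 0.39, STAR 2.7, SAMtools 1.9, featureCounts and edgeR were used with the human build hg38/GRCh38. The order and settings of these tools, the annotation release and whether counting used strand are not given in the sources used here.

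The deposited counts were whole numbers of reads per gene, which the authors had not normalised. Each table listed 78724 genes, of which 2090 shared a symbol with another entry. Those that passed the low-count filter were tested and counted like other genes, but the rule for naming left out shared symbols. Entries with a shared symbol held between 0.0606% and 0.122% of a library's counts. The authors also deposited tables of log2 CPM values with 16257 genes in the inhibitor table and 16852 in the knockout table. For genes with a unique symbol, these deposited log2 values differed from edgeR log2 CPM values with TMM factors and a prior count of 2 by at most 0.00919 and 0.00439 (medians 0.00265 and 0.00252). The counts were used for all main tests and the log2 values for an alternative. Columns were matched to samples by name, and 0 columns belonged to no sample.

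Groups were taken from the labels: untreated, DB2115 at 8 h and DB2115 at 20 h with 4 libraries each, and scramble control and PU.1 knockout with 3 libraries each. Pairs of libraries within a group differed by more than counting noise (chi-square per degree of freedom between 2.58 and 18.4), as repeat libraries of 1 culture would too. Each library was counted as a replicate because the labels number them so. Total counts for replicates 1 to 4 of the inhibitor table were 39563733, 46636588, 50417853 and 35933427 in untreated cells, 33493292, 52389196, 51256395 and 48199851 at 8 h and 47925073, 31854059, 43960562 and 37605855 at 20 h. In the knockout table they were 21582198, 24293120 and 22258714 for scramble and 25670773, 21836376 and 25196142 for knockout replicates 1 to 3. A floor of 3 counts corresponded to between 0.0573 and 0.139 CPM in a single library, and floors cover counting error only because reads are not independent molecules.

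Tests were run in R 4.3.3 with edgeR 4.0.16. Genes were filtered with filterByExpr (minimum count 10, minimum total 15), leaving 16257 genes in the inhibitor table and 16925 in the knockout table. Libraries were scaled with TMM (factors 0.963 to 1.04 and 0.988 to 1.01). The common biological coefficient of variation was 4.50% in the inhibitor table and 8.60% in the knockout table. Each table was fitted separately with glmQLFit and tested with the quasi-likelihood F-test, with all groups of a table sharing the estimate of spread. The p-values were adjusted by Benjamini and Hochberg over all genes tested and called under 0.05. Standard errors were obtained as the size of the log2 change divided by the square root of F. The design, the processing alternatives, the 29 gene lists and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, two-sided, for lists with at least 5 tested members, and adjusted over lists.

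SPI1 was always named. For each comparison, the 6 largest rises and the 6 largest falls were named (4 each between the DB2115 times) among called genes with a symbol. Clone names, antisense genes and ribosomal pseudogenes were left out, and a mean of at least 5 CPM in the higher group and no overlap between groups were required. For each list reported or with at least 3 called members, up to 3 called members with the smallest p were named (4 for main themes), and up to 1 that was not called. For the overlap of knockout and DB2115, the 6 genes per direction with the smallest larger p and 3 of each opposite kind were named. CD36 lay under the level of that rule and was chosen after its values were seen, because its control group held 0 counts. The RNA classes used to describe the libraries and the mitochondrial genes outside the rule were likewise chosen after their values were seen. Some genes that met the rule are not reported here, and counts of list members and of named genes include them.

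The knockout and DB2115 effects were compared by their overlap and by an interaction contrast over all 18 libraries and the 14675 genes tested in both tables. Genes called in the knockout were tested as sets in DB2115 by fry, as planned, and also by camera, which was not planned. Independent lists were taken as the product of the list sizes over the genes tested in both, which treats every gene as equally likely to be called. The shared untreated libraries of the DB2115 comparisons were weighed by 20 simulated experiments with unchanged groups and by splitting the controls. Coordinates came from GENCODE release 29 on GRCh38, which may differ from the annotation of the counts.

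The tests were run first on simulated counts with 50 genes at each of 4 fold sizes (48 or 49 for the difference of effects). These genes were drawn from those with an expected count above 50, and far fewer genes changed than were called in the data. The shares recovered therefore do not cover genes at lower counts. At folds of 1.25, 1.5, 2 and 4, 86%, 96%, 100% and 100% were recovered for DB2115 at 8 h, and 74%, 90%, 100% and 100% at 20 h. For 20 h against 8 h, 70%, 90%, 98% and 100% were recovered, for the knockout 48%, 68%, 96% and 100%, and for the difference of effects 50%, 73.5%, 89.8% and 100%. Unchanged genes made up 8.36%, 3.95%, 5.34%, 6.49% and 10.6% of calls in that order. A list shifted by a small amount was recovered in the 4 comparisons, and 0, 1, 3 and 0 unshifted lists were called. Alternatives were edgeR RLE, upper-quartile and no composition factors, no low-count filter, a stricter filter of 5 CPM, DESeq2 1.42.0, limma-voom, limma-trend on the deposited log2 values, a robust fit, a fit of the compared groups alone, a replicate block, fry, stricter thresholds for overlaps and leaving out each library in turn. Other human samples named in the protocols were not analysed here.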

Results

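RNA was sequenced in 18 samples of MDS-L, an established human line derived from a myelodysplastic syndrome that was grown with IL-3 at 10 ng/mL. In the inhibitor experiment, cells were left untreated or given DB2115, an inhibitor of the transcription factor PU.1, at 3 µM for 8 h or 20 h, with 4 samples per group. The harvest time of the untreated cells and any vehicle are not given in the sources used here. In the knockout experiment, cells edited by CRISPR/Cas9 against PU.1 were set against cells carrying a scrambled guide, with 3 samples per group. The knockout cells are labelled as bulk populations. Both experiments asked which transcripts depend on PU.1, which is encoded by SPI1 and directs myeloid gene expression. Total counts ran from 31854059 to 52389196 per library in the inhibitor experiment and from 21582198 to 25670773 in the knockout experiment. The labels do not say whether the samples of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

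The libraries of the 2 experiments differed in the kinds of RNA they held. RN7SL1, a signal recognition particle RNA without a poly(A) tail, lay between 6.90 and 17.9 CPM, counts scaled to library size, in the 12 inhibitor libraries and between 4359 and 6498 CPM in the 6 knockout libraries. The linker histone gene H1-4, whose mRNA mostly lacks a poly(A) tail, lay between 0.125 and 0.418 CPM in the inhibitor libraries and between 422 and 484 CPM in the knockout libraries. MT-RNR2, the large mitochondrial rRNA, lay between 11019 and 30446 CPM in the inhibitor libraries and between 0.453 and 14.6 CPM in the knockout libraries. For this reason the experiments were compared by changes against each experiment's own controls. Numbers in parentheses after a gene symbol are log2 fold changes ± SE from edgeR, and all genes named as risen or fallen had an adjusted p under 0.05. The largest changes named for each comparison are those among genes with a level of at least 5 CPM in the higher group and no overlap of the groups, so genes at lower levels can have larger fitted changes. Counts of list members given as up, down or not passing refer to the test over all genes, and the p-values of lists are from camera.

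SPI1 mRNA was measured in every library first, because it encodes the protein that the edit targets. SPI1 lies on chromosome 11 from 47354860 to 47378576 on the minus strand of GRCh38, as annotated in GENCODE release 29. The 3 libraries of scramble cells held 164.4, 173 and 173 CPM of SPI1 and the 3 knockout libraries held 79.9, 78.3 and 70.6 CPM, without overlap. SPI1 fell by 1.16 on the log2 scale in the knockout (SE 0.06, edgeR adjusted p = 3.49e-17), to 44.9% of the control level. A small edit can leave mRNA in place, so this level measures neither PU.1 protein nor the share of edited cells. SPI1 in the untreated cells averaged 189 ± 3.45 CPM (SD, n = 4), against 214 ± 6.98 CPM after 8 h and 199 ± 12.3 CPM after 20 h of DB2115 (SD, n = 4 each). The rise at 8 h was small (0.18 ± 0.038, adjusted p = 3.78e-04) and the difference at 20 h did not pass (0.074 ± 0.039, adjusted p = 0.0950). It passed when the TMM factors were left out (0.09, adjusted p = 0.00653), without a low-count filter (0.087, adjusted p = 0.0407) and without 20 h replicate 1 (0.10, adjusted p = 0.0200). Between 8 h and 20 h SPI1 changed by -0.10 ± 0.038 on the log2 scale (adjusted p = 0.0254). That call was lost without 8 h replicate 1 or 4 (adjusted p = 0.11 and 0.0667) or 20 h replicate 1, 3 or 4 (0.106, 0.0528 and 0.0724). It was also lost in a fit of these groups alone (0.0536) and with a replicate block (0.0526).

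**Figure D1:**
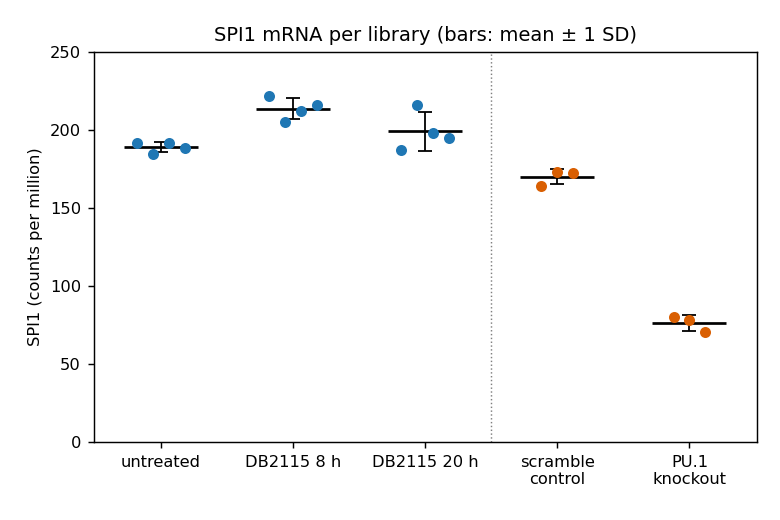
SPI1 mRNA in CPM (vertical axis, starting at 0) in each of the 18 libraries, by group; points are libraries, horizontal bars are group means and vertical bars are ± 1 SD. The 3 knockout libraries lie between 70.6 and 79.9 CPM, and the scramble libraries lie between 164.4 and 173 CPM.

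In the PU.1 knockout, genes of myeloid identity fell and genes of cytokine signalling and ribosome assembly rose. By the rule above, the largest falls were in PLXNC1 (-3.37 ± 0.20), a semaphorin receptor, DHRS9 (-3.17 ± 0.35), a retinol dehydrogenase, COL14A1 (-3.14 ± 0.36), a collagen, PLD4 (-2.98 ± 0.22), an endolysosomal nuclease, LILRA2 (-2.85 ± 0.24), an activating leukocyte receptor, and PRG2 (-2.84 ± 0.26), the eosinophil major basic protein. The largest rises were in ALB, the serum albumin gene, which went from 0.187 ± 0.179 to 5.48 ± 0.641 CPM (4.82 ± 0.44), GJA1 (3.69 ± 0.42), a gap junction protein, the hair keratins KRT86 (3.00 ± 0.28) and KRT81 (2.68 ± 0.32), ITGB3 (2.36 ± 0.23), the platelet integrin beta 3, and BHLHE22 (2.30 ± 0.22), a helix-loop-helix transcription factor. KRT81 and KRT86 are close relatives, so reads could be shared between them. Of 16925 genes tested, 3324 changed, 1786 up and 1538 down. Of these 181 rose and 232 fell at least 2-fold, or 57 and 79 with the stricter filter of 5 CPM. The median size of a called change was 0.35 on the log2 scale.

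Receptors, adhesion molecules and signalling proteins of the myeloid lineage were mostly lower. Of the 38 tested members, 1 rose, 28 fell and 9 did not pass (median -0.53, adjusted p = 6.07e-24; 2 and 28 adjusted over the list alone). They included PTPN6 (-0.86 ± 0.042), a phosphatase of inhibitory receptors, the inhibitory receptor LAIR1 (-0.87 ± 0.064) and the adaptor TYROBP (-1.16 ± 0.10). Genes of antigen presentation through MHC class II fell too, 7 of 11 lower, 1 higher and 3 not passing (median -0.96, adjusted p = 1.08e-12; 1 and 7 adjusted over the list alone). Lower members included the master regulator CIITA (-1.52 ± 0.057), the invariant chain CD74 (-1.25 ± 0.066), HLA-DRA (-1.81 ± 0.12) and HLA-DPB1 (-1.12 ± 0.16). Reads of the HLA genes could be shared among relatives. Among granule proteins 6 of 8 fell, 1 rose and 1 did not pass (median -0.26, adjusted p = 1.10e-05; 1 and 6 adjusted over the list alone). PLAC8 (-2.65 ± 0.13) and lysozyme, LYZ (-1.70 ± 0.22), were lower while the cystatin CST7 (1.52 ± 0.13) was higher. Stem and progenitor genes were lower on balance, 16 down, 8 up and 9 not passing (median -0.15, adjusted p = 4.81e-06; 9 and 17 adjusted over the list alone). CD34 (-0.84 ± 0.035), ANGPT1 (-0.82 ± 0.054) and CEBPA (-0.51 ± 0.041) were lower, and SPI1 itself is a member of that list. The calls of these 4 lists held with an estimated correlation (adjusted p = 0.0141, 0.0141, 0.0394 and 0.0348).

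Of the lists that rose, the smallest adjusted p was that of IL-3 receptor, STAT5 target and feedback genes, the pathway on which the line's growth factor acts. Of 35 tested members, 24 rose, 3 fell and 8 did not pass (median 0.35, adjusted p = 2.79e-24; 25 and 3 adjusted over the list alone), and the call held with an estimated correlation (adjusted p = 0.00761). Oncostatin M, OSM (2.06 ± 0.058), the feedback inhibitor CISH (1.12 ± 0.056), the kinase PIM2 (1.63 ± 0.094) and the cyclin CCND3 (0.83 ± 0.04) were all higher. Ribosome biogenesis genes rose by small amounts, 32 of 45 higher, 0 lower and 13 not passing (median 0.20, adjusted p = 3.02e-11; 37 and 0 adjusted over the list alone). They included MYC (0.35 ± 0.034), BOP1 (0.36 ± 0.041), MRTO4 (0.46 ± 0.057) and MYBBP1A (0.32 ± 0.043), and the call held with an estimated correlation (adjusted p = 0.0394).

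Genes of the erythroid and megakaryocyte lineages also moved in the knockout. Among erythroid genes 9 of 27 rose, 2 fell and 16 did not pass (median 0.23, adjusted p = 0.00255; adjusted p = 0.0701 with an estimated correlation). The membrane skeleton gene DMTN (0.68 ± 0.048), the transferrin receptor TFRC (0.23 ± 0.037) and UROD (0.38 ± 0.055) were higher. Megakaryocyte and platelet genes split, 10 up, 5 down and 10 not passing of 25 (11 and 5 adjusted over the list alone). Their median was -0.0072 while their mean was 0.58, or 0.46 with CD36 at its bound, and the test gave a rise (adjusted p = 0.00200, and adjusted p = 0.224 with an estimated correlation). GFI1B (1.04 ± 0.051), F2RL3 (1.31 ± 0.10) and ITGB3 were higher. CD36 had 0 counts in the 3 scramble libraries together and 283 counts in the 3 knockout libraries, which made it at least 89.3-fold higher against a floor of 3 counts over the control group. Among mast cell, basophil and eosinophil genes 6 rose, 4 fell and 11 did not pass (median 0.049, adjusted p = 0.872; 6 and 5 adjusted over the list alone). FCER1A (1.10 ± 0.14) was higher and SLC45A3 (-1.60 ± 0.056) was lower.

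Smaller shifts were spread over metabolic and stress lists. Cholesterol synthesis genes rose in 10 of 24 cases and fell in 0, with 14 not passing (median 0.18, adjusted p = 7.40e-04; adjusted p = 0.0606 with an estimated correlation). Higher were SQLE (0.53 ± 0.038) and HMGCS1 (0.53 ± 0.068). Unfolded protein response and ATF4 target genes rose in 17 cases, fell in 1 and did not pass in 19 (median 0.17, adjusted p = 2.73e-05; adjusted p = 0.224 with an estimated correlation). DDIT4 (0.64 ± 0.053) and TRIB3 (0.72 ± 0.084) were higher. Heat shock genes gave 8 up, 0 down and 12 not passing (median 0.14, adjusted p = 0.00146; adjusted p = 0.224 with an estimated correlation). HSPA8 (0.44 ± 0.037) was higher. Nuclear respiratory chain genes gave 14 up, 0 down and 64 not passing (median 0.13, adjusted p = 0.00156; adjusted p = 0.224 with an estimated correlation). Myeloid transcription factors fell by the test with 6 up, 10 down and 10 not passing (median -0.0084, adjusted p = 0.00163; adjusted p = 0.0676 with an estimated correlation). GFI1 (-0.96 ± 0.08) and TFEC (-0.90 ± 0.081) were lower beside SPI1 and CEBPA. S phase genes passed narrowly, 14 up, 3 down and 39 not passing (median 0.049, adjusted p = 0.0440; adjusted p = 0.490 with an estimated correlation). That call was lost without scramble replicate 3 (adjusted p = 0.0813) or knockout replicate 1 (adjusted p = 0.120), and without TMM factors (adjusted p = 0.0706).

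The other lists did not pass in the knockout, though single members did. The counts up, down and not passing were 2, 4 and 13 for MHC class I (median -0.11, adjusted p = 0.728) and 3, 5 and 32 for interferon response genes (median -0.014, adjusted p = 0.833, mean 0.015, test pointing down). They were 6, 8 and 17 for NF-kappaB and inflammation genes (median 0.03, adjusted p = 0.833; the mean was 0.017 and the test pointed down). The counts were 5, 6 and 14 for immune ligands and checkpoints (median 0.077, adjusted p = 0.781, mean -0.0038, test pointing down). Lymphoid markers gave 4, 4 and 8 (median 0.049, adjusted p = 0.126), and stromal and epithelial markers gave 1, 2 and 8 (median -0.19, adjusted p = 0.833). The counts were 5, 7 and 6 for ETS family factors (median -0.10, adjusted p = 0.109) and 6, 5 and 15 for BCL2 family and caspase genes (median 0.047, adjusted p = 0.141). The p53 targets gave 7, 5 and 17 (median -0.024, adjusted p = 0.460, mean 0.038, test pointing up). Lysosomal genes gave 5, 10 and 32 (median -0.003, adjusted p = 0.833), and mitotic genes gave 6, 4 and 46 (median 0.013, adjusted p = 0.833), with the sign of the mitotic median turning negative under library-size and upper-quartile scaling. Mitochondrially encoded genes gave 0, 2 and 11 (median -0.18, adjusted p = 0.107), but passed without scramble replicate 2 (adjusted p = 1.88e-12). Ribosomal protein genes gave 12, 1 and 64 (median 0.059, adjusted p = 0.0510) and passed without scramble replicate 1 or knockout replicate 3 (adjusted p = 0.00152 and 0.00353). Replication-dependent histone genes gave 5, 0 and 50 (median 0.062, adjusted p = 0.0978) and passed without scramble replicate 1 or 3 or knockout replicate 3 (adjusted p = 0.00146, 0.00345 and 0.0134). Adjusted over the list alone, the number up or down in any list of the knockout comparison differed by at most 5 from the count over all genes. Called members included the cell cycle inhibitor CDKN1A (1.24 ± 0.092), the survival genes BCL2 (0.64 ± 0.039) and BCL2L1 (0.63 ± 0.048), IL1B (-0.89 ± 0.083), IRF1 (-0.65 ± 0.079) and perforin, PRF1 (1.21 ± 0.061).

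After 8 h of DB2115, myeloid receptors and inflammatory genes were already lower and S phase genes slightly higher, and myeloid transcription factors were lower with the preset correlation alone. By the same rule, the largest falls were in RGS1 (-2.89 ± 0.19) and RGS16 (-2.79 ± 0.075), regulators of G-protein signalling, the fructose transporter SLC2A5 (-2.40 ± 0.16), the collagen COL5A2 (-2.32 ± 0.066), the sodium-proton exchanger SLC9A9 (-2.30 ± 0.13) and the early growth response factor EGR3 (-2.21 ± 0.12). The largest rises were in BHLHE22 (3.02 ± 0.13), carbonic anhydrase 2, CA2 (2.27 ± 0.036), the Rab escort protein CHML (1.78 ± 0.033), the opsin OPN3 (1.73 ± 0.055), the transcription factor OLIG1 (1.72 ± 0.078) and CAVIN2 (1.61 ± 0.045), a caveolar protein. CHML lies within the span of OPN3 on the same strand, so reads could be shared between them. CA2 went from 28.4 ± 1.10 to 137 ± 3.34 CPM (SD, n = 4 each). Of 16257 genes tested, 9241 changed, 4730 up and 4511 down. The median size of a called change was 0.37 on the log2 scale. At least 2-fold, 317 genes rose and 694 fell, or 76 and 174 with the stricter filter of 5 CPM.

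Among myeloid receptors and adhesion genes 28 of 41 fell, 2 rose and 11 did not pass (median -0.36, adjusted p = 8.71e-09; 2 and 28 adjusted over the list alone). LAIR1 (-1.16 ± 0.043), the lectin receptor CLEC12A (-1.73 ± 0.093) and the integrin ITGAX (-1.32 ± 0.071) were lower. NF-kappaB and inflammation genes gave 9 up, 15 down and 11 not passing (median -0.29, adjusted p = 0.00350; 9 and 16 adjusted over the list alone). The NF-kappaB cofactor BCL3 (-1.86 ± 0.045), the subunit RELB (-1.58 ± 0.059) and ICAM1 (-0.63 ± 0.036) were lower and IL1B (0.71 ± 0.039) was higher. S phase genes rose in 35 of 56 cases, fell in 8 and did not pass in 13 (median 0.20, adjusted p = 1.73e-05; 35 and 8 adjusted over the list alone). The nuclease EXO1 (1.26 ± 0.032) and RRM2 (0.59 ± 0.033) were higher. These 3 lists also passed with an estimated correlation (adjusted p = 0.0442, 0.0442 and 0.0212).

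Another 10 lists passed with the preset correlation and not with an estimated one. Myeloid transcription factors fell in 18 of 28 cases and rose in 6, with 4 not passing (median -0.41, adjusted p = 1.07e-05; adjusted p = 0.0615 with an estimated correlation). RUNX3 (-1.54 ± 0.048) went from 970.2 ± 22.3 to 334 ± 23.7 CPM, and IRF1 (-0.99 ± 0.037) and KLF6 (-0.81 ± 0.045) were lower. IL-3 and STAT5 genes fell in 24 cases and rose in 9, with 3 not passing (median -0.31, adjusted p = 1.07e-05; adjusted p = 0.138 with an estimated correlation). FOSB (-2.0 ± 0.063), IL2RA (-1.78 ± 0.064) and ETV5 (-1.19 ± 0.051) were lower and OSM (1.13 ± 0.032) was higher. ETS factors fell in 12 of 20 cases and rose in 4, with 4 not passing (median -0.21, adjusted p = 6.24e-05; adjusted p = 0.141 with an estimated correlation). Lower members included ELK3 (-1.43 ± 0.043), ETV6 (-0.65 ± 0.031) and ETV4 (-1.15 ± 0.077). Granule proteins gave 1 up, 7 down and 2 not passing (median -0.56, adjusted p = 5.35e-04; adjusted p = 0.138 with an estimated correlation). Serglycin, SRGN (-0.88 ± 0.039), and cathepsin G, CTSG (-0.84 ± 0.062), were lower. Mitotic genes gave 7 up, 30 down and 19 not passing (median -0.11, adjusted p = 0.00845; adjusted p = 0.335 with an estimated correlation). KIF2C (-0.37 ± 0.03) and KIF20A (-0.52 ± 0.046) were lower. Interferon response genes gave 7 up, 18 down and 16 not passing (median -0.12, adjusted p = 0.0451; adjusted p = 0.141 with an estimated correlation). TRIM22 (-1.09 ± 0.046) and MX2 (-0.63 ± 0.037) were lower. The interferon call was lost without 8 h replicate 2 (adjusted p = 0.0534), without TMM factors (adjusted p = 0.0521) and with a replicate block (adjusted p = 0.0534).

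Lists of protein homeostasis and ribosome genes passed at 8 h and lost their calls with an estimated correlation. Heat shock genes rose in 15 of 20 cases, fell in 2 and did not pass in 3 (median 0.32, adjusted p = 4.83e-07; adjusted p = 0.146 with an estimated correlation). HSPH1 (1.06 ± 0.032) and HSPA8 (0.98 ± 0.04) were higher. Unfolded protein response and ATF4 target genes gave 12 up, 17 down and 8 not passing (median -0.059, adjusted p = 0.0400; adjusted p = 0.474 with an estimated correlation). The stress regulator DDIT4 (-1.59 ± 0.038), the cystine transporter SLC7A11 (-1.79 ± 0.068) and asparagine synthetase, ASNS (-1.22 ± 0.047), were lower while the chaperone cofactor SDF2L1 (1.11 ± 0.045) was higher. Ribosome biogenesis genes rose in 32 of 45 cases, fell in 3 and did not pass in 10 (median 0.17, adjusted p = 4.17e-05; adjusted p = 0.391 with an estimated correlation). POLR1E (0.80 ± 0.046) and RRP9 (0.57 ± 0.034) were higher and RRP1B (-0.65 ± 0.036) was lower. Ribosomal protein genes fell in 65 of 78 cases, rose in 1 and did not pass in 12 (median -0.19, adjusted p = 3.89e-05; adjusted p = 0.575 with an estimated correlation). Lower members included RPL5 (-0.35 ± 0.037) and RPL10A (-0.33 ± 0.035).

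The remaining lists did not pass at 8 h. Counts up, down and not passing were 3, 5 and 5 for MHC class II (median -0.15, adjusted p = 0.726) and 2, 7 and 10 for MHC class I (median -0.05, adjusted p = 0.204). Immune ligands gave 5, 11 and 10 (median -0.25, adjusted p = 0.134), and megakaryocyte genes gave 5, 11 and 11 (median -0.16, adjusted p = 0.351). The counts were 4, 10 and 8 for mast cell and basophil genes (median -0.11, adjusted p = 0.213) and 13, 15 and 7 for stem and progenitor genes (median -0.23, adjusted p = 0.351). Lymphoid markers gave 3, 6 and 11 (median -0.15, adjusted p = 0.511) and stromal and epithelial markers gave 1, 7 and 5 (median -0.33, adjusted p = 0.334). The p53 targets gave 10, 13 and 6, with a median of 0.02 that turned negative under upper-quartile scaling, a mean of -0.12 and a test pointing down (adjusted p = 0.113). Erythroid genes gave 11, 11 and 5, with a median of -0.20, a mean of 0.022 and a test pointing up (adjusted p = 0.224). BCL2 family and caspase genes gave 10, 13 and 3 (median -0.16, adjusted p = 0.511) and lysosomal genes gave 21, 16 and 10 (median 0.039, adjusted p = 0.334). Nuclear respiratory chain genes gave 15, 22 and 41 (median -0.02, adjusted p = 0.741) and histone genes gave 0, 7 and 31 (median -0.24, adjusted p = 0.274). Cholesterol genes gave 13, 8 and 3 (median 0.093, adjusted p = 0.0581) and passed without 8 h replicate 2 or 3 (adjusted p = 0.0285 and 0.0442). Mitochondrially encoded genes gave 9, 1 and 3 (median 0.42, adjusted p = 0.169) and passed without 8 h replicate 2 (adjusted p = 0.00592). Adjusted over the list alone, the numbers up or down at 8 h differed by at most 2 in any list.

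After 20 h the called changes were larger at the median and covered inflammatory, cholesterol, mast cell and erythroid genes. The metalloproteinase AMZ1 went from 6.70 ± 1.05 to 0.0343 ± 0.0297 CPM, RGS1 from 5.93 ± 0.640 to 0.101 ± 0.128 CPM and the membrane protein TMEM156 from 5.24 ± 0.378 to 0.140 ± 0.0782 CPM (SD, n = 4 each). For RGS1 at 20 h, replicate 2 held 0.292 CPM and the other libraries between 0.0262 and 0.0452 CPM, under the floor of 3 counts. MYCT1 (-5.21 ± 0.11), the dendritic cell lectin CLEC9A (-4.50 ± 0.23) and COL5A2 (-4.26 ± 0.081) were the other large falls by the same rule. The largest rises were in SMIM35 (4.73 ± 0.18), the potassium channel KCNK17 (4.38 ± 0.12), RAB7B (4.27 ± 0.18), the matrix metalloproteinase MMP9 (3.75 ± 0.16), the pseudokinase TRIB2 (3.52 ± 0.058) and the mitochondrial tRNA gene MT-TF (3.47 ± 0.11). Of 16257 genes tested, 10953 changed, 5564 up and 5389 down. Among these 900 rose and 1390 fell at least 2-fold, or 274 and 424 with the stricter filter of 5 CPM. The median size of a called change was 0.51 on the log2 scale.

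The S phase list rose in nearly all members at 20 h, 51 of 56 genes up, 2 down and 3 not passing (median 0.65, adjusted p = 1.56e-26; 51 and 2 adjusted over the list alone). EXO1 (1.85 ± 0.032), CDC45 (0.94 ± 0.03) and MCM3 (0.92 ± 0.031) were higher. Erythroid genes rose in 16 of 27 cases, fell in 6 and did not pass in 5 (median 0.32, adjusted p = 2.93e-04; 16 and 6 adjusted over the list alone). CA2 lay at 283 ± 4.58 CPM against 28.4 ± 1.10 CPM untreated (3.32 ± 0.037), and the erythroid master regulator GATA1 (2.44 ± 0.10), TAL1 (1.09 ± 0.048) and the delta globin gene HBD (1.03 ± 0.044) were higher. Cholesterol synthesis and uptake genes fell in 15 of 24 cases, rose in 4 and did not pass in 5 (median -0.41, adjusted p = 7.54e-07; 4 and 15 adjusted over the list alone). Lower members included INSIG1 (-1.49 ± 0.033), HMGCS1 (-1.24 ± 0.039) and SC5D (-1.01 ± 0.035). NF-kappaB and inflammation genes fell in 22 of 35 cases, rose in 5 and did not pass in 8 (median -0.48, adjusted p = 6.89e-05; 5 and 23 adjusted over the list alone). RELB (-3.30 ± 0.07), BCL3 (-1.83 ± 0.045) and interleukin 8, CXCL8 (-3.90 ± 0.12), were lower and TNFAIP2 (1.14 ± 0.036) was higher. Myeloid transcription factors fell in 18 of 28 cases, rose in 7 and did not pass in 3 (median -0.64, adjusted p = 1.72e-05; 7 and 18 adjusted over the list alone). Lower members included RUNX3 (-1.61 ± 0.048), KLF6 (-1.33 ± 0.047), MEF2C (-1.23 ± 0.044) and the vitamin D receptor VDR (-1.0 ± 0.038). Mast cell and basophil genes gave 6 up, 11 down and 5 not passing (median -0.37, adjusted p = 0.00593; 6 and 11 adjusted over the list alone). HPGD (-2.07 ± 0.05), the high-affinity IgE receptor chain FCER1A (-2.74 ± 0.086) and IL1RL1 (-2.23 ± 0.073) were lower and SIGLEC6 (0.70 ± 0.033) was higher. The p53 targets gave 11 up, 13 down and 5 not passing (12 and 13 adjusted over the list alone). Their values had a median of -0.01, positive under library-size scaling, a mean of -0.27 and a fall by the test (adjusted p = 7.78e-04). Among them BTG2 (-1.96 ± 0.034), ZMAT3 (-1.59 ± 0.042) and RRM2B (-1.42 ± 0.04) were lower. These 7 lists also passed with an estimated correlation, at adjusted p = 7.29e-06, 0.0407, 0.0418, 0.0108, 0.0483, 0.0483 and 0.0281 in the order given.

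Another 11 lists passed only with the preset correlation. Myeloid receptors and adhesion genes fell in 21 of 41 cases, rose in 11 and did not pass in 9 (median -0.11, adjusted p = 3.63e-04; adjusted p = 0.133 with an estimated correlation). Cathepsin S, CTSS (-3.64 ± 0.084), the kinase LYN (-1.30 ± 0.039) and the G-CSF receptor CSF3R (-1.21 ± 0.036) were lower. Granule proteins gave 3 up, 7 down and 0 not passing (median -0.71, adjusted p = 6.89e-05; adjusted p = 0.0611 with an estimated correlation). CTSG (-2.81 ± 0.074) and PLAC8 (-3.67 ± 0.12) were lower. Interferon response genes gave 11 up, 22 down and 8 not passing (median -0.31, adjusted p = 0.00593; adjusted p = 0.0721 with an estimated correlation). CMPK2 (-1.29 ± 0.032), TRIM22 (-1.94 ± 0.049) and IFI44 (-2.94 ± 0.15) were lower. IL-3 and STAT5 genes gave 8 up, 22 down and 6 not passing (median -0.46, adjusted p = 3.03e-04; adjusted p = 0.169 with an estimated correlation). FOSB (-3.26 ± 0.072) and JUN (-2.48 ± 0.089) were lower and ID1 (1.16 ± 0.041) and OSM (0.88 ± 0.032) were higher. ETS factors gave 6 up, 12 down and 2 not passing (median -0.31, adjusted p = 0.00235; adjusted p = 0.202 with an estimated correlation). ELK3 (-1.78 ± 0.044) and ELF1 (-1.05 ± 0.036) were lower. Unfolded protein response and ATF4 targets gave 13 up, 20 down and 4 not passing (median -0.31, adjusted p = 1.37e-04; adjusted p = 0.210 with an estimated correlation). ASNS (-2.75 ± 0.052), SLC7A11 (-3.02 ± 0.076) and DDIT4 (-2.37 ± 0.041) were lower. Heat shock genes gave 14 up, 4 down and 2 not passing (median 0.41, adjusted p = 3.90e-06; adjusted p = 0.157 with an estimated correlation). HSPH1 (1.22 ± 0.032), FKBP4 (1.02 ± 0.037) and HSPE1 (1.05 ± 0.041) were higher.

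Lists of translation, respiration and chromatin also moved at 20 h. Ribosomal protein genes fell in 71 of 78 cases, rose in 3 and did not pass in 4 (median -0.37, adjusted p = 2.07e-08; adjusted p = 0.449 with an estimated correlation). Lower members included RPL22 (-0.72 ± 0.036) and RPS20 (-0.70 ± 0.047). Nuclear respiratory chain genes rose in 51 of 78 cases, fell in 3 and did not pass in 24 (median 0.21, adjusted p = 3.03e-04; adjusted p = 0.449 with an estimated correlation). Higher members included ATP5MC1 (0.77 ± 0.038) and NDUFB10 (0.74 ± 0.057). Replication-dependent histone genes gave 1 up, 19 down and 18 not passing (median -0.60, adjusted p = 0.00217; adjusted p = 0.0939 with an estimated correlation). H2AC6 (-1.72 ± 0.047) and H2BC21 (-2.03 ± 0.089) were lower. Ribosomal protein genes have many processed pseudogenes that can share their reads, and histone genes are near-identical copies whose mRNA was scarce in the inhibitor libraries. Megakaryocyte and platelet genes gave 9 up, 12 down and 6 not passing (10 and 12 adjusted over the list alone). Their median was 0.065, their mean -0.052, and the test gave a fall (adjusted p = 0.0339; adjusted p = 0.280 with an estimated correlation). The ATP receptor P2RX1 (-1.93 ± 0.052) and RAB27B (-1.22 ± 0.044) were lower.

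The other lists did not pass at 20 h. Counts up, down and not passing were 4, 8 and 1 for MHC class II (median -0.47, adjusted p = 0.347) and 6, 10 and 3 for MHC class I (median -0.24, adjusted p = 0.462). CD74 (-0.58 ± 0.046) and HLA-DPB1 (-0.69 ± 0.057) of class II and HLA-E (-1.18 ± 0.035) of class I were lower. RFXAP (1.24 ± 0.10) of the class II list and CALR (1.47 ± 0.043) of the class I list were higher. Immune ligands gave 11, 9 and 6, with a median of 0.13, a mean of -0.10 and a test pointing down (adjusted p = 0.756). CD200 (-3.04 ± 0.11) and HAVCR2 (-3.50 ± 0.18) were lower. Lymphoid markers gave 4, 7 and 9, with a median of -0.016, positive under library-size scaling, a mean of -0.12 and a test pointing up (adjusted p = 0.994). Among them PRF1 (1.67 ± 0.043) was higher and PAX5 (-1.52 ± 0.087) lower. Stromal and epithelial markers gave 3, 9 and 1 (median -0.66, adjusted p = 0.119). PDGFRA (3.27 ± 0.17) was higher and VWF (-1.36 ± 0.072) lower. Stem and progenitor genes gave 13, 18 and 4 (median -0.10, adjusted p = 0.464) and mitotic genes gave 26, 16 and 14 (median 0.068, adjusted p = 0.415). BCL2 family and caspase genes gave 12, 13 and 1 (median -0.042, adjusted p = 0.290) and ribosome biogenesis genes gave 23, 15 and 7 (median 0.083, adjusted p = 0.710). Lysosomal genes gave 19, 15 and 13 (median 0.073, adjusted p = 0.654) and mitochondrially encoded genes gave 3, 7 and 3 (median -0.21, adjusted p = 0.347). ADGRG1 (1.13 ± 0.041) and HOXB4 (1.07 ± 0.039) rose among stem cell genes and BCL2A1 (-2.14 ± 0.05) fell among BCL2 family genes. Adjusted over the list alone, the numbers up or down at 20 h differed by at most 1 in any list.

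**Figure D2:**
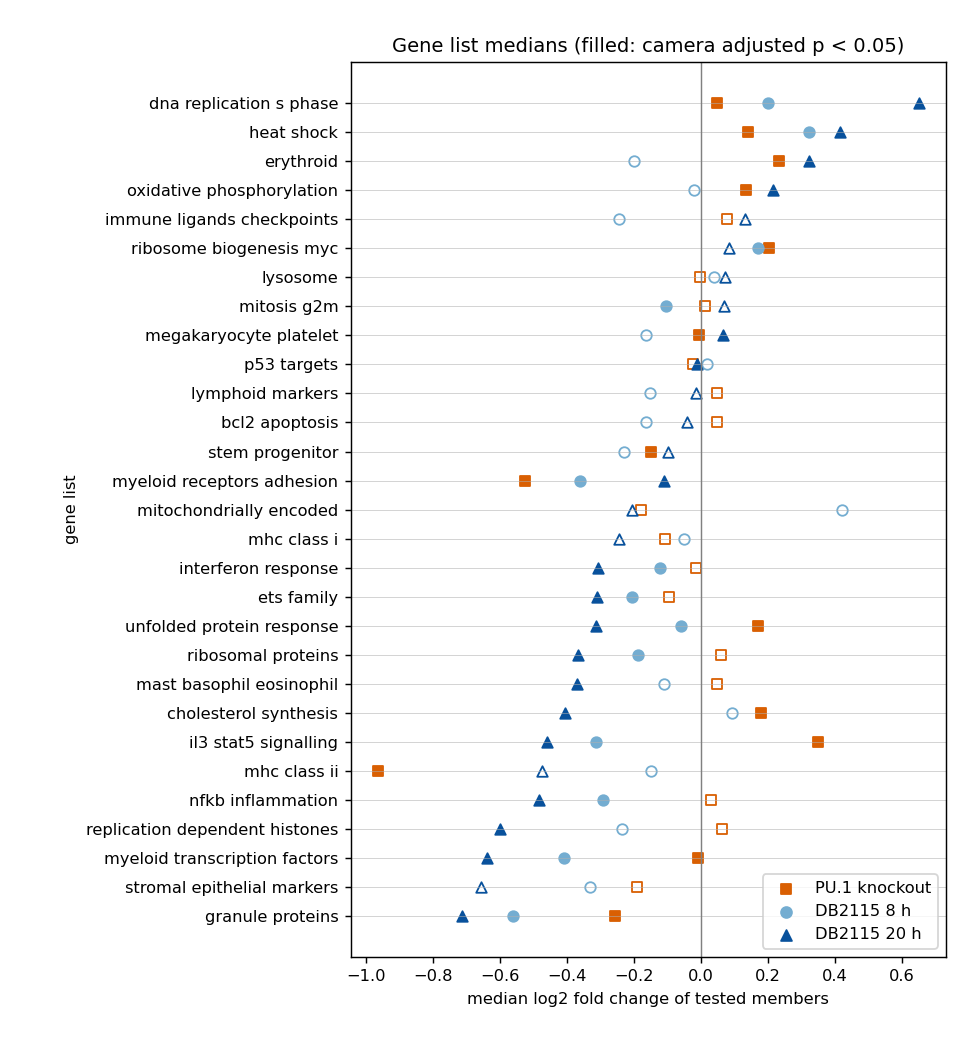
Median log2 fold change (horizontal axis) of each of the 29 gene lists (vertical axis) for the knockout against scramble control and for DB2115 at 8 h and 20 h against untreated cells; filled symbols mark lists called by camera at an adjusted p under 0.05 and open symbols lists that were not. The IL-3 and STAT5 list lies at 0.35 in the knockout and at -0.46 at 20 h of DB2115, and the S phase list at 0.049 and 0.65.

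Between 8 h and 20 h of DB2115 the S phase list rose further, the erythroid list rose and cholesterol genes turned from mixed to lower. By the same rule the largest rises were in the mitochondrial genes MT-TF (3.80 ± 0.11), MT-RNR1 (3.32 ± 0.073) and MT-TV (3.06 ± 0.11) and in KCNK17 (3.05 ± 0.10). MT-RNR1 went from 607 ± 67.8 to 6081 ± 569 CPM. Whether the counting used strand is not given in the sources used here, so overlapping mitochondrial transcripts cannot be told apart with certainty. The largest falls were in MYCT1 (-4.32 ± 0.12), argininosuccinate synthase, ASS1 (-2.90 ± 0.064), PLAC8 (-2.85 ± 0.13) and CTSS (-2.79 ± 0.087). In all, 9440 of 16257 genes differed, 4589 higher and 4851 lower at 20 h. Of these 595 and 638 differed at least 2-fold, or 129 and 131 with the stricter filter of 5 CPM. S phase genes were higher in 52 of 56 cases and lower in 1, with 3 not passing (median 0.45, adjusted p = 5.06e-25; 52 and 1 adjusted over the list alone). Cholesterol genes were lower in 19 of 24 cases and higher in 2, with 3 not passing (median -0.62, adjusted p = 1.14e-20; 2 and 20 adjusted over the list alone). Erythroid genes gave 16 up, 5 down and 6 not passing (median 0.25, adjusted p = 1.53e-04; 16 and 5 adjusted over the list alone). The p53 targets gave 8 up, 16 down and 5 not passing (median -0.24, adjusted p = 0.00356; 8 and 16 adjusted over the list alone), and NF-kappaB genes 7 up, 18 down and 10 not passing (median -0.25, adjusted p = 0.00727; 7 and 18 adjusted over the list alone). These 5 lists passed with an estimated correlation (adjusted p = 2.25e-05, 0.00178, 0.0177, 0.0381 and 0.0433).

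A further 9 lists differed between the times only with the preset correlation. Higher at 20 h were mitotic genes (median 0.17, adjusted p = 1.54e-04; adjusted p = 0.189 with an estimated correlation) and nuclear respiratory chain genes (median 0.23, adjusted p = 1.55e-07; adjusted p = 0.398 with an estimated correlation). Among them 37 of 56 and 60 of 78 members were up and 8 and 3 were down. Lower were ribosome biogenesis genes (median -0.20, adjusted p = 0.00104; adjusted p = 0.498 with an estimated correlation) and ribosomal protein genes (median -0.17, adjusted p = 3.35e-04; adjusted p = 0.691 with an estimated correlation). Among them 32 of 45 and 55 of 78 members were down and 7 and 2 were up. Lower too were unfolded protein response and ATF4 targets (median -0.10, adjusted p = 0.00124; adjusted p = 0.370 with an estimated correlation) and mitochondrially encoded genes (median -0.51, adjusted p = 0.00468; adjusted p = 0.551 with an estimated correlation). Among them 18 of 37 and 11 of 13 members were down and 9 and 1 were up. Histone genes (median -0.48, adjusted p = 0.00281; adjusted p = 0.101 with an estimated correlation), mast cell genes (median -0.32, adjusted p = 0.0161; adjusted p = 0.0776 with an estimated correlation) and granule proteins (median -0.19, adjusted p = 0.0273; adjusted p = 0.304 with an estimated correlation) were lower, with 15 of 38, 11 of 22 and 5 of 10 members down and 1, 5 and 4 up. Megakaryocyte genes did not pass with all libraries (median 0.14, mean 0.043, test pointing down, adjusted p = 0.0558) and passed without 8 h replicate 2 or 4 (adjusted p = 0.0379 and 0.0412). Adjusted over the list alone, the numbers higher or lower between the times differed by at most 2 in any list.

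The 2 times shared many changed genes. Among the genes tested, 3300 were called higher at both times, against 1619 for independent lists of those sizes, and 3103 were lower at both, against 1495. Opposite calls numbered 1031, against 3112. The comparisons share their 4 untreated libraries. With these split 2 and 2 between the comparisons, on average 2797 genes were higher and 2560 lower at both times, against 1293 and 1158 for independent lists. Across genes, which are not independent replicates, the log2 changes at 8 h and 20 h had a Pearson correlation of 0.667 and a covariance of 0.284. Simulated groups with no change against the same controls gave on average a correlation of 0.496 and a covariance of 0.0189, and splitting the controls 2 and 2 between the comparisons gave 0.587 and 0.268.

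The knockout and DB2115 were then set against each other to ask whether editing of PU.1 and the inhibitor moved the same genes. Among genes higher in both were the cytokine LIF (2.18 ± 0.074 in the knockout and 2.08 ± 0.067 with DB2115), the hypoxia factor EPAS1 (0.98 ± 0.046 and 1.06 ± 0.034), and PRF1 (1.21 ± 0.061 and 1.67 ± 0.043). So were OSM (2.06 ± 0.058 and 0.88 ± 0.032), the sialyltransferase ST3GAL4 (0.86 ± 0.049 and 1.23 ± 0.032) and the receptor chain IL2RB (2.08 ± 0.067 and 0.98 ± 0.041). Among genes lower in both were the mTOR regulator DEPTOR (-1.82 ± 0.048 and -1.74 ± 0.042), FRY (-0.97 ± 0.042 and -1.68 ± 0.045), and the receptor CALCRL (-1.43 ± 0.066 and -3.07 ± 0.07). PLAC8 (-2.65 ± 0.13 and -3.67 ± 0.12), GPR85 (-1.29 ± 0.064 and -1.22 ± 0.043) and ATP8B4 (-0.87 ± 0.043 and -0.75 ± 0.034) were also lower in both. Single genes also moved in opposite directions. The growth factor CSF1 (0.95 ± 0.04 and -0.96 ± 0.033), COL5A2 (1.98 ± 0.11 and -4.26 ± 0.081) and the superoxide dismutase SOD2 (0.72 ± 0.053 and -0.69 ± 0.036) were higher in the knockout and lower with DB2115. The lectin SIGLEC10 (-1.34 ± 0.049 and 1.13 ± 0.039) and ABHD2 (-0.47 ± 0.038 and 0.82 ± 0.041) did the reverse.

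**Figure D3:**
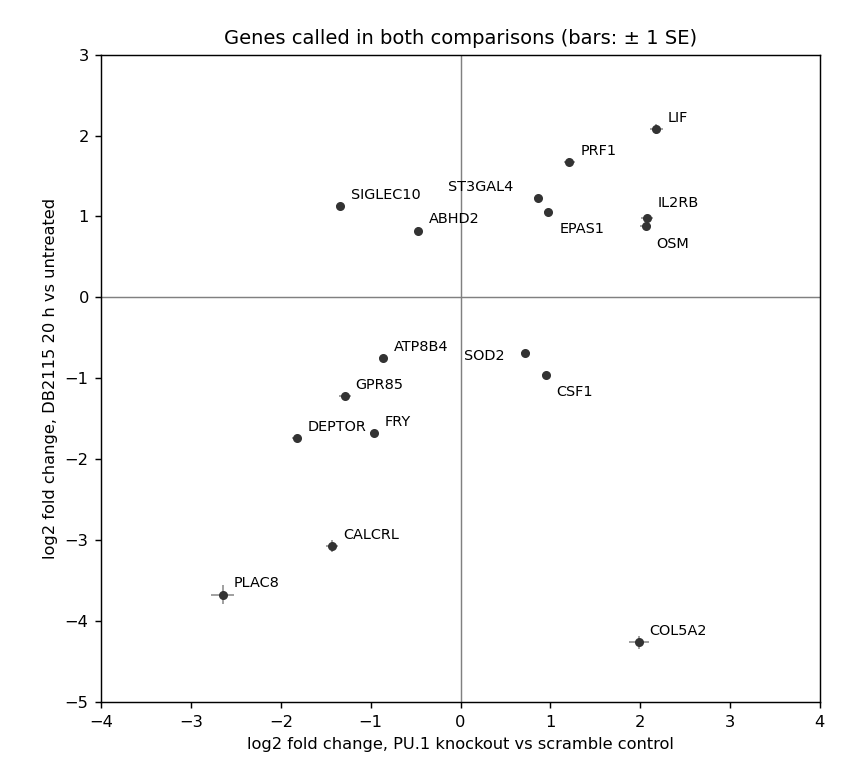
Log2 fold changes of 17 genes in the PU.1 knockout (horizontal axis, 3 against 3 libraries) and after 20 h of DB2115 (vertical axis, 4 against 4 libraries), with bars of ± 1 SE; the genes are those named for the overlap of the 2 comparisons, so each was called in both. Genes in the upper right and lower left moved the same way, and COL5A2 lies in the lower right at 1.98 and -4.26.

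Of 14675 genes tested in both, 2596 were called in both, 1588 in the same direction (61.2%) and 1008 in opposite directions. The 864 genes higher in both exceeded the 641 given by independent lists, and the 724 lower in both exceeded 490. Independent lists take every gene as equally likely to be called. Gene level was not matched, so part of an excess could come from that. The 569 genes higher in the knockout and lower with DB2115 did not differ from the 603 of independent lists by Fisher's exact test (p = 0.0691). The 439 of the reverse kind were fewer than 521 (Fisher p = 1.85e-06). Across genes the changes had a Pearson correlation of 0.123 and a Spearman correlation of 0.125, and genes are not independent replicates. As a set, genes lower in the knockout had a median of -0.14 with DB2115 at 20 h, 724 of 1440 lower and 439 higher (fry adjusted p = 5.24e-08; camera adjusted p = 4.61e-04, or 0.123 with an estimated correlation). At 8 h the median was -0.13, 704 lower and 368 higher (fry adjusted p = 2.02e-07; camera adjusted p = 3.45e-05, or 0.0626 with an estimated correlation). Genes higher in the knockout had a median of 0.09 at 20 h, 864 of 1772 higher and 569 lower, called by fry (adjusted p = 0.00339) and not by camera (adjusted p = 0.193). At 8 h their median was 0.047, 752 higher and 556 lower, without a call by either test (adjusted p = 0.151 and 0.384). At 8 h of DB2115 the overlap with the knockout held 752 genes higher in both and 704 lower in both, more than the 559 and 420 of independent lists. The 556 genes higher in the knockout and lower with DB2115 at 8 h also exceeded the 517 of independent lists, while the 368 of the reverse kind were fewer than 454.

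A test of the difference between the knockout effect and the 20 h effect called 7832 of the 14675 genes. The knockout effect was higher in 3972 and lower in 3860. All 1008 genes called in opposite directions were among them, which such calls made nearly certain. A split that kept the DB2115 groups and mixed the knockout and scramble libraries called 6735 genes, so much of the count follows from DB2115. The fit shared the estimate of spread over all 18 libraries, though the coefficient of variation was 4.50% in the inhibitor table and 8.60% in the knockout table. The IL-3 and STAT5 list differed most clearly among the lists with a higher knockout effect (median difference 0.63, adjusted p = 1.05e-15; adjusted p = 3.29e-04 with an estimated correlation). Its members PIM2 and CISH differed by 0.94 ± 0.084 and 1.61 ± 0.054. The difference exceeded the rise in the knockout for CISH and not for PIM2. With DB2115 the fitted change was thus a fall for CISH and a smaller rise for PIM2. Cholesterol (0.57, adjusted p = 5.03e-10), unfolded protein response (0.38, adjusted p = 4.95e-10), NF-kappaB (0.48, adjusted p = 9.93e-04), megakaryocyte (0.53, adjusted p = 1.12e-04), p53 (0.20, adjusted p = 9.93e-04) and mast cell genes (0.51, adjusted p = 0.0127) had a higher knockout effect. These 6 lists also passed with an estimated correlation (adjusted p = 6.58e-04, 0.0147, 0.00856, 0.0147, 0.0147 and 0.0312). The S phase list had a lower knockout effect (-0.56, adjusted p = 1.16e-17), as did MHC class II (-0.54, adjusted p = 0.00201), both also with an estimated correlation (adjusted p = 3.29e-04 and 0.0147). Another 8 lists passed only with the preset correlation, with adjusted p from 0.0948 to 0.387 with an estimated correlation. For myeloid receptors the difference did not pass (median 0.0098, test pointing down, adjusted p = 0.290), nor did it for erythroid genes (-0.024, adjusted p = 0.20). The experiments differed in time, in control and in the RNA classes of their libraries, so a difference of effects is a difference between these experiments.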

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

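The tests between 8 h and 20 h and of other splits were planned, while the measures and genes searched for a library far from its group were chosen only after the result was seen. Library measures and the levels of genes whose group values are printed were examined in 48 groups of 4 libraries. In 2 of them a library stood far from the others by Dixon's 95% criterion, and chance gives about 1 in 20. RGS1 at 20 h was at 0.292 CPM in replicate 2 and between 0.0262 and 0.0452 CPM in the other libraries. Those other values lay under the floor of 3 counts in a single library, so this gap rests on few reads. RUNX3 in untreated cells was at 936.9 CPM in replicate 3 and between 978 and 984 CPM in the others. Groups of 3 were not examined in this way.

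The effect of DB2115 differed between 8 h and 20 h by a test of the difference itself in 9440 genes and 14 gene lists. Of 168 genes named in the report, 18 were called in opposite directions against untreated cells at the 2 times and differed between them. Higher at 20 h than at 8 h were MT-RNR1 (3.32 on the log2 scale), KRT86 (2.42), PRF1 (2.11), LILRA2 (1.88), CDC45 (1.02), PLD4 (0.82), SIGLEC6 (0.79) and CIITA (0.38). Lower at 20 h were IL1RL1 (-2.60), GPR85 (-1.45), HMGCS1 (-1.33), IL1B (-1.22), PLXNC1 (-1.03), ATP8B4 (-0.83), ANGPT1 (-0.78), SLC45A3 (-0.74), TFRC (-0.55) and MYC (-0.38). Some of these opposite calls rest on small changes at one time, such as ATP8B4 (0.077 ± 0.033) and CDC45 (-0.081 ± 0.031) at 8 h. PRF1 was at -0.44 ± 0.046 at 8 h and 1.67 ± 0.043 at 20 h, and IL1B at 0.71 ± 0.039 and -0.51 ± 0.041.

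Other splits of the same libraries were counted for each comparison. For gene counts of DB2115, only the real split, 1 of 35, gave a count as large. This held at 8 h (9241 genes, highest other 0), at 20 h (10953, highest other 0) and between the times (9440, highest other 0). These zeros are from edgeR at an adjusted p under 0.05. A mixed split moves the difference between the groups into the spread, so few calls were likely whatever set the groups apart. The counts thus follow the real groups but cannot tell an effect of DB2115 from a difference between cultures. At an unadjusted p under 0.05 the highest other splits gave 2237, 2054 and 3108 genes, against 9862, 11335 and 10020 in the real ones. For gene lists, the real split, 1 of 35, gave the most lists at 8 h (13, highest other 12), at 20 h (18, highest other 10) and between the times (14, highest other 11). Mixed splits thus called up to 12 lists, and 1 of 35 is the smallest share possible here. The list counts by themselves therefore do not exclude chance, least of all at 8 h with a margin of 1 list. For the difference of knockout and 20 h effects, 1 of 100 splits, the real one, gave as many genes (7832). The highest other split gave 6735 genes and kept the real DB2115 groups with mixed knockout groups, and the highest without the real DB2115 groups gave 1019. Of the 100 splits, 2 kept the real DB2115 groups. The count thus follows the DB2115 and untreated groups, whose difference the other splits again moved into the spread. These splits therefore do not exclude chance for the DB2115 groups, and they say nothing about it for the knockout and scramble libraries. For the knockout, the 6 libraries allow 10 splits, which are too few for a share under 0.05. The real split, 1 of 10, gave 3324 genes and 14 lists and the highest others gave 0 genes and 11 lists (5112 and 397 genes at an unadjusted p under 0.05).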

How the results depend on the processing

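Leaving out both shallow DB2115 libraries together, and setting the knockout against 8 h in place of 20 h, were the tests chosen only after the result was seen. Over the planned settings other than leaving out a library, the count of changed genes ran from 7288 to 9346 at 8 h, 7989 to 11370 at 20 h, 7464 to 9457 between the times and 3105 to 3464 in the knockout. The lowest DB2115 counts came from the stricter low-count filter, under which fewer genes were tested. That filter left 76 genes rising and 174 falling at least 2-fold at 8 h, 274 and 424 at 20 h, 129 and 131 between the times and 57 and 79 in the knockout. Leaving out 1 library at a time gave 8692 to 9018 genes at 8 h (4229 to 4561 higher, 4236 to 4629 lower) and 10563 to 10857 at 20 h (5325 to 5520 higher, 5209 to 5337 lower). It gave 8978 to 9259 between the times (4378 to 4699 higher, 4503 to 4750 lower) and 2558 to 2929 in the knockout (1276 to 1607 higher, 1249 to 1322 lower). The number of lists ran from 13 to 14, 18 to 18, 14 to 15 and 13 to 16. In the knockout at least 73.7% of the calls were kept in the same direction without any 1 library. Without both shallow libraries, 8 h replicate 1 and 20 h replicate 2, 94.8%, 95.9% and 92.5% of calls were kept at 8 h, at 20 h and between the times, and stromal markers passed at 20 h (adjusted p = 0.0499). No called result turned its direction under any setting tried.

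The list calls depended most on the test. With an estimated correlation 3 lists passed at 8 h, 7 at 20 h, 5 between the times and 6 in the knockout. The fry test, which does not compare a list with other genes, called 27, 24, 25 and 17 in that order. SPI1 at 20 h passed at 0.090 without composition factors, and the cause was not tested. At an adjusted p under 0.01 in both, 510 genes were higher in knockout and DB2115 and 635 went in opposite directions, and at least 1.5-fold in both 110 were higher, 177 lower and 170 opposite. The share in the same direction ran from 60.7% to 62.8% over the settings tried. At an adjusted p under 0.01 at both times, 651 genes had opposite calls at 8 h and 20 h. These falls follow from the stricter thresholds. Across scalings the share of called genes that were higher ran from 46.2% to 51.7% at 8 h, 47.9% to 52.6% at 20 h and 48.1% to 53.8% in the knockout. Of 405 named gene results that were called, 395 stayed called under every setting that tested the gene, and 10 were lost under at least 1. Genes that a setting left untested, as the stricter filter did for genes at low levels, were not counted as lost.

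Replicate numbers did not pair the samples. Deviations from group means correlated between -0.503 and 0.274 over the 12 same-numbered pairs of the inhibitor table and between -0.00207 and 0.0391 over the 3 of the knockout table. Pairs with different numbers reached 0.494 and 0.0377, so not every sample correlated best with its own number. The value of 0.494 was reached by 8 h replicate 1 with 20 h replicate 2 and by 8 h replicate 2 with 20 h replicate 1. Replicates 2 of both times were at -0.503. Some spread was thus shared across groups apart from the numbers, and its source was not tested. With the number as a replicate block, 8945, 10716, 9149 and 3464 genes and 12, 18, 14 and 17 lists passed for 8 h, 20 h, 20 h against 8 h and the knockout, and 7739 genes for the difference of effects. Interferon genes at 8 h then missed the threshold (adjusted p = 0.0534), as did SPI1 between the times (0.0526). In the knockout, mitochondrially encoded (0.0321), ribosomal protein (0.0373) and histone genes (0.0450) passed. Depth limited genes under the floor of 3 counts. Small folds were recovered less often in the simulated knockout counts than in those of DB2115, which differ in depth, group size and spread, and these were not varied singly.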

Other observations

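The tests on mitochondrial transcripts, on immediate early genes, on the shallow libraries, on the size of called changes and on sets of genes at least 2-fold changed in the knockout were chosen only after the result was seen, and the genes named here were chosen after their values were seen. Transcripts of the mitochondrial genome moved by strand and position with DB2115. All 8 tested light-strand genes were lower at 8 h (median -1.81, from -3.66 to -1.27) and at 20 h (median -2.25, from -5.08 to -0.95). Among them the protein-coding MT-ND6 (-2.10 ± 0.098 and -1.84 ± 0.098) stood at 109 CPM in untreated cells. The others were tRNA genes at 0.566 to 3.81 CPM in untreated cells. MT-TA, which gave the lowest values, averaged 0.0222 CPM at 20 h, under the floor of 3 counts in a single library. The 4 genes next to the heavy-strand promoter, MT-TF, MT-RNR1, MT-TV and MT-RNR2, rose at 20 h (median 3.00, from 1.28 to 3.47), while at 8 h 1 was higher, 1 lower and 2 did not pass (median -0.19). Of the 20 other heavy-strand genes, 10 rose and 2 fell at 8 h (median 0.27), and 3 rose and 12 fell at 20 h (median -0.25). Mitochondrial rRNA made up 1.17% to 1.28% of counts in untreated libraries and 3.29% to 3.71% at 20 h.

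Immediate early genes outside the IL-3 list, short-lived transcripts of growth and stress signals, fell with DB2115 and rose in the knockout. Of 29 tested, 20 fell, 2 rose and 7 did not pass at 8 h (median -0.53, limma camera adjusted p = 4.59e-13; adjusted p = 0.00793 with an estimated correlation). At 20 h 20 fell, 3 rose and 6 did not pass (median -0.88, adjusted p = 7.64e-14; adjusted p = 0.00793 with an estimated correlation). In the knockout 10 of 27 rose, 1 fell and 16 did not pass (median 0.21, adjusted p = 1.65e-04; adjusted p = 0.0409 with an estimated correlation). EGR1 was at -3.42 ± 0.15 at 20 h and 1.55 ± 0.33 in the knockout, and RGS16 at -3.68 ± 0.084 and 2.27 ± 0.18. Genes at least 2-fold lower in the knockout were on balance lower at 8 h, 92 of 175 lower and 29 higher (median -0.35, camera adjusted p = 3.08e-04; adjusted p = 0.0446 with an estimated correlation). At 20 h 94 were lower and 45 higher (median -0.49, adjusted p = 5.28e-04; adjusted p = 0.0977 with an estimated correlation), and fry called this set lower at both times (adjusted p = 5.33e-08 and 1.09e-08). Genes at least 2-fold higher in the knockout leaned lower at 8 h, 39 of 170 higher and 59 lower (median -0.10), called by fry (adjusted p = 1.87e-06) and not by camera (adjusted p = 0.0979). At 20 h 67 were higher and 59 lower (median 0.047), without a call by either (adjusted p = 0.249 and 0.870).

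For the mitochondrial pattern 3 technical explanations were weighed, and the tables argue against mitochondrial DNA and scaling between libraries. Carry-over of RNA without a poly(A) tail would raise histone genes and RN7SL1 alike. Their median was -0.57 at 20 h, though RN7SL1 itself rose (0.41 ± 0.15, adjusted p = 0.0209). The histone genes set that median and their mRNA was scarce in these libraries, so it cannot decide on carry-over. Mitochondrial DNA in the libraries would raise both strands, while the light-strand median was -2.25. Under the other scalings MT-RNR1 stayed at or above 3.12. Carry-over, a change in the tails of mitochondrial RNA, which poly(A) selection would turn into a change of counts, and the untested strand setting of the counting stay open. As a hypothesis, DB2115 may alter transcription or turnover of mitochondrial RNA, which was not tested.

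The IL-3 and STAT5 list rose in the knockout and fell with DB2115, with a median difference of effects of 0.63. The fall lost its call with an estimated correlation (adjusted p = 0.138 at 8 h and 0.169 at 20 h), while the rise (0.00761) and the difference (3.29e-04) kept theirs. Scaling between libraries is argued against, since the lowest median difference under other scalings was 0.58. Different starting levels in the controls stay open. Relative to all genes the list stood 0.65 higher in untreated than in scramble libraries, above 99.9% of 10000 random lists, but this cannot be told apart from the difference in RNA classes between the libraries of the 2 experiments. A fall of short-lived transcripts with DB2115 is also consistent with the immediate early genes outside the list (median -0.88 at 20 h), so an opposite action of knockout and inhibitor on this pathway is only a candidate explanation.

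At 20 h of DB2115, 67.4% of the tested genes changed. A trend on GC content and gene length is argued against as the whole cause, because its removal left 10558 genes called against 10486 before, over the 93.6% of genes with values. The removal shifted the balance from 5409 higher and 5077 lower to 5830 and 4728 at 20 h, and from 4631 and 4345 to 5086 and 3932 at 8 h, so the share of called genes that were higher depends on it. The shallow libraries are argued against as well, since 10956 genes were called without them. Many of the called changes were small, as 43.7% of the called genes changed at least 1.5-fold, and how far low spread between libraries led to their calls was not tested. A biological effect of DB2115, and of culture between the unstated harvest of untreated cells and 20 h, stays open.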
